A study of Homo sapiens with 6 samples.

How the data were processed

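Anti-TY ChIP-seq was measured in 6 samples, 3 of untagged WT and 3 of CFAP20-KO cells with TY-CFAP20. Per the labels' protocols, cells were crosslinked with DSG and formaldehyde, and the WT reactions held more chromatin and more Drosophila spike-in chromatin than the TY-CFAP20 reactions. The submitters' processing notes name Trim Galore 0.6.5, BWA 0.7.17, SAMtools 1.11, HOMER 4.8.2, STAR 2.7.7a and R 4.0.5, the human build hg38 and the Drosophila build BDGP6, without saying which tool made which value. How the spike-in factor was computed is not given in the sources used here.

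The authors deposited 1 table of read density signal for each group, already averaged over replicates and normalised to the spike-in, so replicates could not be compared. Every deposited signal value was a sum of whole multiples of 3 steps per group (0.0233, 0.0417 and 0.0967 in WT, 0.0425, 0.0667 and 0.100 in TY-CFAP20). Dividing the mean density by the largest and the smallest step bounds the number of fragments per position. It does not give library totals. Density falls at the upstream edge, to 0.235 in WT. A table of the authors holds TSS coordinates with the BrU-seq signal in WT, and another the origin centres. How those centres were selected is not given in the sources used here. The deposited tables also hold a DRIP signal, and a ratio whose header names CFAP20 over WT but not the assay. That ratio, deposited by the authors, is used in the closing section alone. No column of per-sample values was left without a sample or group (0 such columns).

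From these tables, the mean density from -500 to 500 bp was taken per TSS, with the outermost 1 kb on each side as flank. Differences are TY-CFAP20 minus WT. Log2 ratios used a pseudocount of 0.668, the median WT flank density, which understates the ratio of TSSs with low density. Classes held equal numbers of TSSs. Near and far TSSs had an origin centre within 10 kb or none within 50 kb. Lists and near-origin TSSs were set against 10000 random sets of the same size matched on BrU-seq in 20 strata, and percentiles describe these averages without testing the conditions. Coordinates are hg38, 1-based. The GENCODE annotation and the hg38 sequence gave biotypes and promoter GC and CpG content. Of the 3000 TSSs, 2584 lay within 100 bp of an annotated start of the same gene. The running flank ratio is the summed flank density of 11 neighbouring TSSs in TY-CFAP20 over that in WT.

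Named genes followed a rule fixed before the data were examined, as were the lists, windows and most alternatives. It took the 12 largest differences, the 6 largest log2 ratios among the most transcribed genes not already taken, the 4 most negative differences, the 3 highest WT densities, and in each list the 2 largest and the smallest difference. CFAP20 and CCNC were also to be named and are not analysed here. Some genes that the rule takes are not reported here.

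On simulated densities for the 3000 TSSs, all 98 TSSs given the smaller bump and all 99 given the larger were recovered at 2-fold, and 0 of 2800 left alone were. Both bumps were set well above 2-fold, and the simulated noise was drawn only once per TSS. These counts therefore check the calculation and give no error rate for the 2-fold count in the real data. Of 30 TSSs in a lowered block, 28 were found in a low stretch. Of 2000 random gene lists, 121 fell outside the percentiles 2.5 to 97.5, where 100 would be the nominal number. Alternatives covered the window, scaling to the flanks, the TSSs used, the pseudocount, the threshold, the distance to origins and the matching. Scaling by the running flank ratio, leaving out the low stretches or chromosome 10, a count without pseudocount, and matching on gene length or CpG content were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.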

Results

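Chromatin immunoprecipitation with an antibody against the TY epitope was followed by sequencing in RPE1 cells, an immortalised human retinal pigment epithelium line, here a derivative with inducible Cas9 and without p53. The 6 libraries fell into 2 groups of 3. WT cells carried no TY tag, so their signal is the background of the antibody. The other group lacked endogenous CFAP20, a cilium-associated protein that the study also examines in the nucleus, and expressed TY-tagged CFAP20. The values used here are the authors' averages over each group, so no replicate error, n or p-value can be given, and every difference below compares 2 averages. They cover 3000 transcription start sites (TSSs) of 3000 gene symbols, in 1001 positions 10 bp apart from 5 kb upstream to 5 kb downstream. These were the 3000 TSSs with the highest BrU-seq level (labelling of nascent RNA, in WT gene bodies) among 9944 listed TSSs. The total number of reads per library is not known from these values. In the TSS window the averages corresponded to between 8.22 and 34.1 overlapping fragments per position in WT and between 13.6 and 32.0 in TY-CFAP20. CFAP20 and CCNC, the genes deleted in parts of the study, are not analysed here.

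The first comparison asked where around start sites tagged CFAP20 lies. TY-CFAP20 density formed a single summit over the TSS, while WT density rose less. Within 500 bp of the TSS the mean spike-in normalised density was 1.36 in TY-CFAP20 and 0.795 in WT, a ratio of 1.71. In the outermost 1 kb on each side, the flanks, it was 0.775 and 0.678, a ratio of 1.14. Density within 500 bp was 1.75 times its own flank level in TY-CFAP20 and 1.17 times in WT. The TSS ratio was 1.497 times the flank ratio. How much the higher GC content of TSS windows contributes to this was not tested. TY-CFAP20 minus WT was highest at -20 bp, where it reached 0.785 against 0.0967 in the flanks. The span above the midpoint between flank and summit ran from -300 to 490 bp. The difference extended further into genes than upstream of them, at 0.327 from 500 to 1000 bp downstream and 0.184 over the same distance upstream. WT dipped just upstream, to 0.739 at -60 bp, and was at 0.756 at the TSS itself, where the TY-CFAP20 mean was 1.54. TY-CFAP20 alone was slightly higher at 60 bp (1.56), so the WT dip moves the largest difference upstream. TY-CFAP20 exceeded WT at 2737 of the 3000 TSSs (91.2%) and in 3978 of 6000 flank windows (66.3%).

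**Figure D1:**
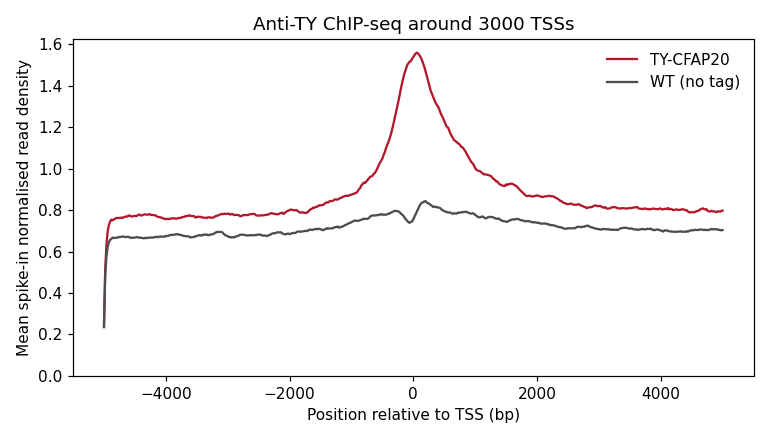
Mean spike-in normalised read density (vertical axis) by position relative to the TSS in bp (horizontal axis) over 3000 TSSs, for the authors' averages of TY-CFAP20 and of untagged WT. TY-CFAP20 reaches 1.54 at the TSS, where WT is at 0.756, and both lines fall off at the upstream edge of the window.

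Over single TSSs the median of TY-CFAP20 minus WT was 0.571, with 25th and 75th percentiles of 0.268 and 0.846. These percentiles describe the spread between TSSs, not an error. With a pseudocount of 0.668, the median WT flank density, 53 TSSs were at least 2-fold higher in TY-CFAP20 (1.77%), against 3 of the 6000 flank windows (0.05%). With this pseudocount no TSS was 2-fold lower. At 1.5-fold the counts were 1048 TSSs and 126 flank windows, and at 3-fold both were 0. The 2-fold count depends on the pseudocount. It was 551 with 0.25 of it and 0 with 4 times it. Without any pseudocount 919 of the 2984 TSSs with a WT density of at least 0.2 passed (30.8%), against 200 of 5958 flank windows (3.36%). Some TSSs were then more than 2-fold lower, among them GS1-124K5.11 (0.301 of WT), TNNT1 (0.305) and RP3-473B4.3 (0.453).

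The 12 genes with the largest differences began with KANSL1-AS1, a non-coding RNA gene on chromosome 17 (TSS at 46193576, hg38), which stood at 3.55 in TY-CFAP20 and 1.25 in WT. NBPF1 followed at 5.42 and 3.17, a ratio of 1.71 as over all TSSs, with high flanks of 3.13 and 2.55. It also had the highest WT density of all TSSs, ahead of ARRB2 (1.64, with 2.86 in TY-CFAP20) and ZFYVE27 (1.61, with 2.34). LCOR, a nuclear receptor corepressor, had 3.40 against 1.40, and SGPL1, the sphingosine-1-phosphate lyase, 2.95 against 0.966. IDE, an insulin-degrading protease, had 3.52 against 1.54. The phosphatase gene DUSP5, an immediate-early gene (chromosome 10, 110497838), had 3.13 against 1.17. MCMBP, a partner of the MCM replicative helicase, had 3.21 against 1.26, the co-chaperone gene BAG3 3.10 against 1.30, and the deacetylase gene SIRT1 2.83 against 1.09. KB-1732A1.1, COQ2 (coenzyme Q synthesis) and ZNF146 completed the group with differences of 1.84, 1.77 and 1.73. Of the 12 genes, 7 lie on chromosome 10, which holds 148 of the 3000 TSSs (4.93%). Beyond 60 Mb of that chromosome the median WT flank density was 1.51 times, and the TY-CFAP20 flank density 1.58 times, that of other chromosomes. By log2 ratio, only 1 of the 12 highest TSSs was on chromosome 10. ZNF146 lies where the running flank ratio, taken over 11 neighbouring TSSs, was 1.73 against a median of 1.17. After division of TY-CFAP20 by that ratio, the difference at ZNF146 was 0.7515.

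Among the most transcribed genes, the 6 with the highest log2 ratios outside that group included SOWAHC, TXN, TOB2, LGALS1 and SNRNP70. SOWAHC had a log2 ratio of 1.13. TXN, which encodes the redox protein thioredoxin, stood at 1.74 in TY-CFAP20 and 0.478 in WT, LGALS1, which encodes a galectin, at 2.23 and 0.714, and SNRNP70, a component of the U1 splicing particle, at 2.01 and 0.636. TOB2, an antiproliferative gene, had a log2 ratio of 1.07.

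The 4 most negative differences were at GS1-124K5.11 (-0.736), RP3-473B4.3 (-0.680), the muscle troponin gene TNNT1 (-0.625) and CSNK2A1 (-0.589), which encodes a catalytic subunit of casein kinase. All 4 lie in stretches where the flanks were low in TY-CFAP20 as well. After division of TY-CFAP20 by the running flank ratio (local scaling, added after the data were seen) they were -0.620, -0.365, -0.543 and -0.121. With a running flank ratio below 0.75 of its median taken as low, 10 such stretches of 5 or more TSSs held 223 TSSs. The longest on chromosome 7 ran from SYPL1 to ESYT2 (106.1 to 158.8 Mb), that on X from LONRF3 to VBP1 (119.0 to 155.2 Mb), that on chromosome 19 from ZNF175 to ZBTB45 (51.6 to 58.5 Mb) and that on chromosome 20 from ZCCHC3 to ABHD12 (0.297 to 25.4 Mb). The others were on chromosomes 7, 15 and 21. The median difference was 0.0385 in these stretches and 0.602 elsewhere, and the flank ratio 0.685 and 1.18, while the median WT flank density was 0.668 in both. With local scaling the median difference was 0.404 in the stretches and 0.388 elsewhere. Of the 40 most negative differences, 28 were in them.

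**Figure D2:**
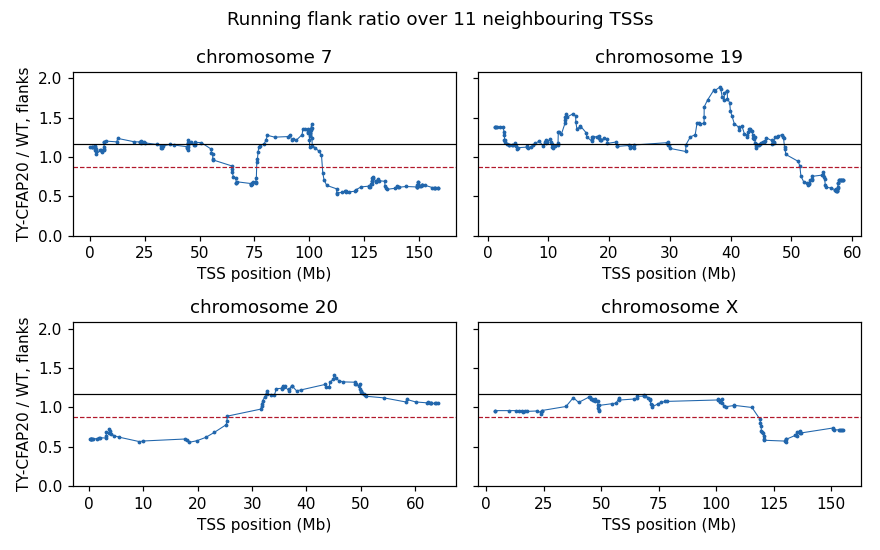
Running ratio of TY-CFAP20 to WT density in the flanks over 11 neighbouring TSSs (vertical axis) by TSS position in Mb (horizontal axis) on chromosomes 7, 19, 20 and X, with each point a TSS, the black line the median of 1.17 and the dashed line the limit of 0.876. The ratio drops below the limit at the ends of chromosomes 7, 19 and X, at the start of chromosome 20 and between 64.8 and 75.8 Mb of chromosome 7, and it is raised around ZNF146 on chromosome 19 (1.73).

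Whether CFAP20 follows transcription was examined by BrU-seq level. The difference was higher at more transcribed genes, by a small amount beside the spread within each class. Over 5 classes of 600 TSSs, the median difference was 0.457, 0.540, 0.579, 0.583 and 0.672 from the lowest to the highest BrU-seq class, while median WT density was 0.748 in the lowest and 0.815 in the highest. In the lowest class the 25th and 75th percentiles were 0.197 and 0.753, in the highest 0.414 and 0.945. The summit was 0.668 high in the lowest class and 0.918 in the highest, at 20 and -60 bp. Across genes, which are not independent replicates, Spearman's rho was 0.168 and Pearson's r 0.129. No TSS without a BrU-seq value is in the density tables. The lowest class still belongs to the 3000 highest levels listed, so little transcribed genes were not compared.

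DRIP, which measures RNA-DNA hybrids (R-loops), was compared because the tables hold a value for each TSS. This comparison was added after the tables were seen. The median difference was 0.469 in the lowest of 5 DRIP classes and 0.624 in the highest, with 0.577, 0.581 and 0.601 between them. The highest class exceeded the lowest by 0.155, or by 0.0835 with local scaling. Across genes rho was 0.130, and DRIP itself rose with BrU-seq (rho 0.400). Within the 5 BrU-seq classes rho lay between 0.0184 and 0.120, and in the second lowest the highest DRIP class was below the lowest, by -0.0130.

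**Figure D3:**
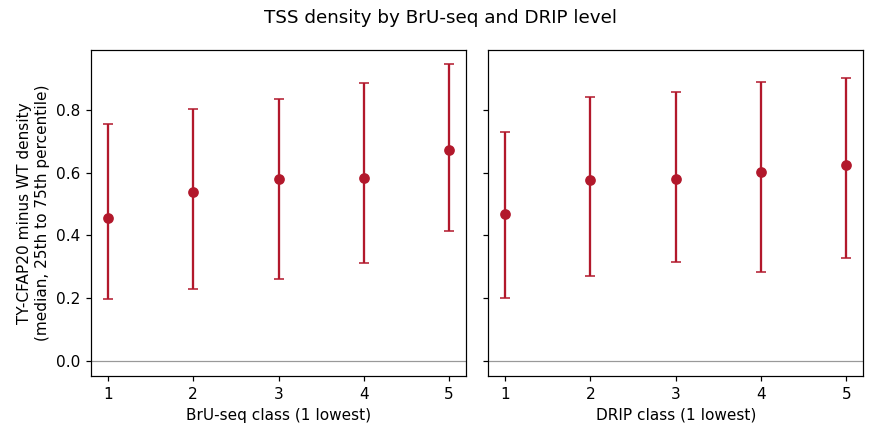
Median of TY-CFAP20 minus WT density within 500 bp of the TSS (vertical axis, points) by class of BrU-seq (left) and DRIP level (right), 600 TSSs per class from lowest to highest, with bars from the 25th to the 75th percentile over TSSs. The medians go from 0.457 to 0.672 by BrU-seq and from 0.469 to 0.624 by DRIP, with wide overlap between classes.

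Replication was examined through origin centres mapped by OK-seq, which sequences Okazaki fragments. Genes near an origin had higher TY-CFAP20. The median difference was 0.659 at the 197 TSSs with a centre within 10 kb. It was 0.549 at the 2419 TSSs with none within 50 kb. Named genes near a centre ranged from LCOR and MCMBP, both on chromosome 10 and among the 12 largest differences, to CALD1 (-0.165). NDUFA12 (0.773) and GINS1 (0.109) lay between them. Random far TSSs matched on BrU-seq had a median of 0.538, and the near-origin median lay at percentile 99.99 of 10000 such sets. Genes near origins were longer, at a median of 33.8 kb against 16.99 kb. Matched on BrU-seq and gene length, a matching added after the data were seen, random sets had a median of 0.602 and the percentile was 92.4. Around the centres themselves, 80 TSS windows could be measured. Within 500 bp of a centre TY-CFAP20 minus WT was 0.199, against 0.160 at the same distances from TSSs without a nearby origin, a difference of 0.0388. In the next distance classes the difference was -0.0197, 0.00354, -0.0192 and 0.0397.

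Of 15 gene lists, 11 had 3 or more measured members. Heat shock genes stood apart. All 5 measured members, of 20 listed, were higher in TY-CFAP20, as were 91.2% of all TSSs. Their median difference was 1.29 against 0.684 in lists matched on BrU-seq (percentile 99.8 of 10000). BAG3 had 1.79, the chaperone gene HSPH1 1.39 and DNAJB1 0.713. With local scaling these were 1.305, 1.08 and 0.208, and the list was at percentile 99.6. BAG3 lies on the part of chromosome 10 with high flanks. For differences within 500 bp, matched on BrU-seq, no other list left the range from 2.5 to 97.5. Of the 15 serum and stress immediate-early genes, all were higher in TY-CFAP20, or 14 with local scaling, and 2 were at least 2-fold higher. Over all TSSs these shares were 91.2%, 87.6% and 1.77%. The median difference of these 15 genes was 0.859 (percentile 91.5), from 1.96 at DUSP5 to 0.178 at FOS, which was at -0.0122 with local scaling. By log2 ratio their percentile was 98.7. CYR61, which encodes a matricellular protein, stood at 2.66 in TY-CFAP20 and 1.16 in WT. Of the 14 ribosomal protein genes, 13 were higher, or 12 with local scaling, with a median of 0.925 (percentile 93.7). The percentile of this list was 99.3 within 250 bp, 79.8 within 1000 bp and 75.3 with local scaling. RPS7 had 1.35, RPS14 1.23 and RPS4X -0.0542, or 0.175 within 250 bp.

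The lists of transcription and replication genes stayed within the range of matched lists in the same setting. The 6 R-loop factors had a median of 0.795 against 0.562 in matched lists (percentile 89.7). Their percentile was 98.9 within 250 bp, 67.3 within 1000 bp, 73.1 with local scaling and 68.4 when also matched on CpG ratio. The helicase genes DDX21, on chromosome 10, and DHX9 were at 1.56 and 1.02, and AQR at 0.286 in a stretch with low flanks. The 7 genes of RNA polymerase II and elongation had 0.574 (percentile 43.6), from CCNT1 (1.18) and CTR9 (0.802) to SUPT5H (0.122, or -0.297 with local scaling). The 6 Mediator genes had 0.533 (percentile 30.4), with MED30 at 0.973, MED18 at 0.955 and MED7 at 0.152, or -0.0355 with local scaling. The 14 genes of origin licensing and the replisome had 0.624 (percentile 55.8), with GMNN at 0.774, MCM10 at 0.749 and GINS1 at 0.109, or -0.140 within 1000 bp. The 6 p53 targets had 0.742 (percentile 67.9), with GADD45A at 0.877, TIGAR at 0.751 and AEN at 0.0637, or -0.0311 with scaling of all TSSs to the flanks. The p53 gene is disrupted in both groups.

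Lower medians were found for cilium genes, oxidative phosphorylation and extracellular matrix, none of them outside the range of matched lists. The 7 cilium genes had 0.253 (percentile 6.86), with MKS1 at 0.953, IFT27 at 0.390 (-0.0265 from 0 to 1000 bp) and KIF7 at 0.137 (-0.00307 with scaling to the flanks). The 15 genes of oxidative phosphorylation had 0.442 (percentile 10.5), with SDHB at 0.957, NDUFA12 at 0.773 and NDUFS5 at 0.0128, or -0.115 with local scaling. The 7 genes of matrix and cytoskeleton had 0.333 (percentile 9.53), with COL12A1 at 1.01 and CALD1, in the low stretch of chromosome 7, at -0.165, or 0.289 with local scaling. Too few members for a percentile were measured of the histones (HIST1H4H 0.780 and HIST1H3E 0.432), the retinal pigment epithelium markers (OTX2 0.222, or -0.111 from 0 to 1000 bp, and MITF -0.0547) and the markers of other lineages (SFTPB 0.129, or -0.000123 with local scaling). No fragile-site gene was among the 3000 TSSs.

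**Figure D4:**
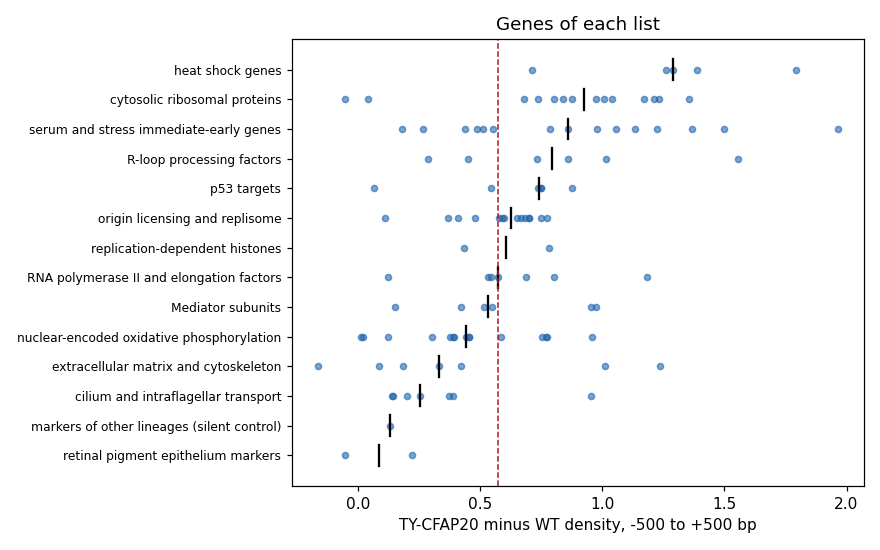
TY-CFAP20 minus WT density within 500 bp of the TSS (horizontal axis) for each measured gene of 14 lists, with a vertical bar at each list's median and a dashed line at 0.571, the median of all TSSs. The 5 heat shock genes lie between 0.713 and 1.79, all to the right of the dashed line.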

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

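The 4 tests in this part were chosen after the results they bear on had been seen. A signal in a column that the report does not use stood out. In the authors' deposited table the ratio headed CFAP20 over WT, whose assay is not named, had a median of 0.766 in the stretches with low TY-CFAP20 flanks and 1.17 elsewhere. By stretch, the median in the authors' deposited table was 0.677 and 0.674 on chromosome 7, 0.653 on chromosome 19, 0.673 on chromosome 20 and 0.905 on X. The stretches on chromosomes 15 and 21 were not all lowered, with medians in the authors' deposited table from 0.992 to 1.54.

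The low stretches themselves were weighed against 3 technical explanations. Mapping, GC or repeat content acting on both groups would lower WT as well, but the WT flank density there was 1.00 times that elsewhere. GC bias of the TY-CFAP20 libraries alone would leave WT unchanged, so this value cannot test it. The median GC of TSS windows was 60.8% in the stretches and 60.4% elsewhere. A single spike-in factor for a library would move every chromosome alike, but the lowest chromosome had 0.726 of the flank ratio of the highest. Fewer DNA copies in the TY-CFAP20 cells remain a candidate explanation. In stretches picked from the upstream flanks alone, the downstream flank ratio was 0.630 of that elsewhere and the TSS ratio 0.633, so background and TSS were lowered alike. A regional loss of background for another reason is not excluded, input DNA is not used here, and no biological explanation was tested.

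The 7 chromosome 10 genes among the 12 largest differences may reflect more chromosome 10 DNA in both groups. WT flank density beyond 60 Mb was 1.51 times that of other chromosomes, while TY-CFAP20 over WT at the TSS was only 1.08 times theirs. After scaling by the running flank ratio, 3 of the 12 largest differences were on chromosome 10. That ratio is TY-CFAP20 over WT, so DNA shared by both groups cancels out, and this count cannot test the explanation. A higher occupancy of some of these genes stays open, and was not tested.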

How the results depend on the processing

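Scaling by the running flank ratio (local scaling), leaving out the low stretches or chromosome 10, the count without pseudocount, matching on gene length or CpG ratio, and all settings of the DRIP comparison were chosen after seeing the data. No paired analysis was possible because the labels number the replicates alike in both groups but the values used here are group averages. Leaving out a replicate was not run for the same reason. Keeping BrU-seq values above 0 or 1 TSS per symbol removed no TSS and says nothing about stability. Depth per library is unknown, so differences between single TSSs have no counting error. Flank scaling lowered the median log2 ratio by -0.13, and 85.3% of TSSs were then above WT.

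The ratio of 1.71 stayed above 1 in every setting. It was 1.88 within 250 bp, 1.52 within 1000 bp and 1.58 from 0 to 1000 bp, 1.497 with flank scaling, 1.501 with local scaling, 1.715 without the 1% of TSSs highest in WT, 1.76 without the low stretches, 1.70 without chromosome 10 and 1.78 as a ratio of medians. The summit moved from -20 to 20 bp with medians and to -60 bp in the highest BrU-seq class. The cause was not tested.

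The count of 53 TSSs at 2-fold depended most on the settings. It was 280 within 250 bp, 2 within 1000 bp, 27 from 0 to 1000 bp, 7 with flank scaling, 16 with local scaling, 551 and 0 with 0.25 and 4 times the pseudocount, 919 without one, 1048 at 1.5-fold and 0 at 3-fold. A larger pseudocount or a stricter threshold lowers it by construction. The cause of the other moves was not tested.

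The highest minus the lowest BrU-seq class, 0.215, stayed positive. It was 0.299, 0.156 and 0.180 in those 3 windows, 0.182 with flank scaling, 0.160 with local scaling, 0.217 without the TSSs highest in WT, 0.210 without the low stretches, 0.137 as log2 ratio and 0.271 with 10 classes. By DRIP it was 0.155, and 0.125 with flank scaling, 0.0835 with local scaling, 0.160 without the low stretches and 0.0839 as the mean within BrU-seq classes.

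Near-origin minus matched TSSs, 0.121, was 0.168, 0.0874 and 0.127 in the 3 windows, 0.106 with flank scaling, 0.108 with local scaling and without the low stretches, 0.122 without the TSSs highest in WT, 0.149 within 5 kb, 0.135 within 25 kb, 0.0635 as log2 ratio and 0.115 when also matched on WT density, all above percentile 97.5. Matched on gene length with BrU-seq or with CpG ratio it was 0.0571 (percentile 92.4) and 0.0455 (percentile 89.2), and 0.0368 (percentile 88.2) and 0.0201 (percentile 76.9) with local scaling as well, so the value is smaller once gene length is matched. Around origin centres 0.0388 became 0.0228 more than 2 kb from listed TSSs, 0.0308 with flank scaling and 0.0505 with local scaling.

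The number of lists outside the matched range went from 1 to 3 within 250 bp and without matching, and to 2 within 1000 bp. It was also 2 by log2 ratio with either other pseudocount, settings that changed the measure and the pseudocount together. Besides heat shock genes, ribosomal proteins left the range, at percentile 99.3 within 250 bp and 99.7 without matching. R-loop factors were at 98.9 within 250 bp. Immediate-early genes were at 98.8 without matching and 99.7 within 1000 bp. By log2 ratio they were at 97.7 with either other pseudocount and already at 98.7 with the main one. Heat shock genes, the one list called, stayed above their matched lists in each setting, at percentiles from 97.8 to 99.96. Lists that were not called did change side of the matched median. Mediator genes went from -0.100 to 0.0754 within 250 bp and 0.0252 with local scaling. RNA polymerase II and elongation went from -0.0193 to 0.167 within 250 bp, 0.130 from 0 to 1000 bp, 0.0583 with local scaling and 0.00246 without matching. Origin licensing and replisome went from 0.0195 to -0.0505 within 1000 bp, -0.0960 from 0 to 1000 bp, -0.0291 with local scaling, -0.0122 without the low stretches and -0.0987 when also matched on CpG ratio.

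Of 530 values under alternatives for the 60 genes that the naming rule takes, 22 changed sign, all in 12 members of gene lists. With local scaling SUPT5H was -0.297, NDUFS5 -0.115, MED7 -0.0355, FOS -0.0122, SFTPB -0.000123 and CALD1 0.289. With flank scaling NDUFS5 was -0.113, AEN -0.0311 and KIF7 -0.00307. Within 250 bp SUPT5H was -0.100 and FOS -0.0126, while RPS4X was 0.175. Within 1000 bp GINS1 was -0.140, AEN -0.0243 and SFTPB -0.0160, while RPS4X was 0.00106. From 0 to 1000 bp GINS1 was -0.226, OTX2 -0.111, AEN -0.0320, IFT27 -0.0265 and SFTPB -0.0105, while RPS4X was 0.321. The cause was not tested.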

Other observations

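TY-CFAP20 differed by promoter type. Protein-coding genes (2527 TSSs) had a median difference of 0.621 and lncRNA genes (409 TSSs) 0.229, with median WT densities of 0.792 and 0.736. Random TSSs matched to the lncRNA genes on BrU-seq had 0.592, and matched on BrU-seq and CpG ratio 0.352. The 459 TSSs with an opposite-strand start within 1 kb upstream had 0.722, against 0.548 in TSSs matched on BrU-seq and 0.633 in TSSs matched on BrU-seq and CpG ratio, above all 10000 random sets in both cases. Their summit was also wider upstream, reaching -430 bp where that of other TSSs reached -290 bp. KANSL1-AS1, IDE, SOWAHC and TOB2 are among them.

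The CpG ratio of the promoter (observed over expected CpG) went with the difference more closely than BrU-seq did, at a Spearman's rho across genes of 0.461 against 0.168. From the lowest to the highest of 5 classes the median difference was 0.185, 0.502, 0.657, 0.728 and 0.743. Long genes had higher values too, 0.693 in the longest class and 0.396 in the shortest, although BrU-seq fell with length (rho -0.413). Within the 3 CpG classes rho with length was 0.157, 0.115 and 0.0293.

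Of the tests of the CpG relation, that in windows away from annotated starts was set before its result was seen, and the other 3 after. More transcription at CpG-rich promoters is argued against as the whole cause, since rho within a BrU-seq class was at least 0.354. Nor do non-coding genes with few CpGs, since rho was 0.361 among protein-coding genes. GC bias of the TY-CFAP20 libraries stays open. From GC-poor to GC-rich flank windows TY-CFAP20 over WT differed 1.499 times, as much as at promoters (1.45 times), but 24 of the 29 GC-rich flank windows lay within 2 kb of an annotated start and may be promoters themselves. In flank windows more than 2 kb from any annotated start the value was 1.15 between the GC bands of 40 to 45% and 55 to 60%, against 1.33 for TSS windows of the same bands. Part of the relation could therefore be GC bias, and the rest cannot be told apart from binding by these averages. The same holds for the TSS ratio of 1.497 times the flank ratio. Of the 6000 flank windows, 5123 counted as GC-poor (up to 52.4% GC). The median GC of TSS windows outside the low stretches was 60.4%. How much of that TSS ratio is GC bias was not tested.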
